A study of Caenorhabditis elegans with 12 samples.

How the data were processed

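The samples are whole L1 larvae of 3 Caenorhabditis elegans strains, N2, HBR2340 and PHX2193, kept in arrest for 48 h, with 4 biological replicates per strain and 12 libraries in all. Total RNA was extracted with Trizol after bead beating and sequenced after a standard Illumina library preparation. The deposited values are gene counts per library, unnormalised whole numbers for 46934 WormBase gene identifiers, made by the authors. Per the submitters' processing notes reads were aligned with Bowtie 0.12.2. Those notes name WBcel235, a Caenorhabditis elegans build, and also mm8, a mouse build, and how the latter was used is not given in the sources used here. The counting program, the annotation release, the strandedness and the handling of reads that map to several places are not given in the sources used here.

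Gene symbols, positions and biotypes came from the Ensembl annotation of WBcel235, which holds 46924 of the identifiers. A symbol was found for 44113 identifiers, and 2821 had none and are named by sequence name or identifier. The 12 protein genes of the mitochondrial genome have no symbols there and were matched by their annotation. In all, 15339 genes had no count in any library. The deposited table was checked for libraries copied from one another. The closest pair within a strain differed by a chi-square per degree of freedom of 10.6.

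Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with few counts were removed with filterByExpr by strain (minimum count 10, minimum total 15), which left 15908 genes and removed 31026. Libraries were scaled with TMM factors. A quasi-likelihood model with 1 term per strain was fitted to all 12 libraries with robust estimation (9 residual degrees of freedom, common biological coefficient of variation 0.276). The 3 comparisons are HBR2340 against N2, PHX2193 against N2 and PHX2193 against HBR2340. Tests are two-sided, and a gene is called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM with TMM scaling, given as mean ± SD of 4 libraries, and log2 CPM used a prior count of 2. The level that 3 counts make in a library is called the floor. Intervals and floors cover counting error only. The 95% Wilson interval of the ribosomal RNA share of N2 B (5.78%) is 5.77% to 5.79%, which shows the precision that these depths give.

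The 42 gene lists were fixed before the data were examined, as were the comparisons, the thresholds, the rule for named genes and the first set of other settings below. They cover flp-11 with 3 channel genes, RIS and GABA neuron genes, K2P channels, FMRFamide-like, neuropeptide-like and insulin-like peptides, antimicrobial peptides, and lysozyme, saposin and lectin genes. They cover genes raised or lowered by DAF-16, heat shock, stress of the endoplasmic reticulum and of mitochondria, SKN-1 linked genes, P450 and conjugation families, HIF-1 targets, autophagy and lysosome, and proteases. They cover lipid catabolism, fatty acid synthesis, glyoxylate cycle with gluconeogenesis and trehalose, glycolysis, collagens, moulting, ribosomal proteins, mitochondrially encoded genes, nuclear respiratory chain genes, cell cycle, histones and L1 arrest regulators. The rest are markers of intestine, body muscle, pharynx, epidermis, neurons, cilia, germ cells, embryo or oocyte, sperm, yolk and ribosomal RNA, and the gpd-2 operon. Each list was tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, lists of at least 3 tested genes, with Benjamini-Hochberg adjustment over the 42 lists, and again with an estimated correlation. Counts of called members were also adjusted over the list alone.

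The named genes are flp-11, egl-23, unc-58 and twk-18, and in each comparison the 10 called genes with the largest rise and the 10 with the largest fall. These had to have a mean log2 CPM of at least 1 and all 4 libraries of one strain above all 4 of the other. From each list up to 2 called members with the smallest adjusted p were added, or up to 2 members with the smallest p where the list passed with none called. For genes called in both strains with the same sign, the 10 with the smallest larger adjusted p were taken. Genes named outside this rule were picked after their values were seen, and the text says so there.

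The first set of other settings was DESeq2 size factors and upper quartile factors in edgeR, no filter, a filter of 10 counts in 4 libraries, DESeq2 1.42.0, limma-voom, only the 8 libraries compared, a replicate block, each library left out in turn, and a fit without robust estimation. For the comparison of both strains, the N2 libraries were also split in 6 ways and the threshold was set to 0.01 and 0.1. Settings chosen after seeing the data were limma-voom with sample quality weights, removal of the D libraries of N2 and PHX2193, removal of these and N2 B, the comparison of both strains without N2 B, and the lists without N2 B with an estimated correlation. Unchanged groups were simulated 100 times against the same N2 libraries. Fisher's exact tests were one-sided, and the interval of a median came from order statistics. Random lists numbered 10000 and were drawn from 20 bins of expression, and gene classes had at least 8 tested members. Ratios to other libraries used a pseudocount of 0.5 CPM. The ranking of single genes in N2 B used genes with a mean of at least 2 CPM in the other N2 libraries. Shares of genes and list medians used all tested genes.

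The pipeline was tested on simulated data with 15705 genes tested. It recovered 63 of 100 genes changed 2-fold and 94 of 100 changed 4-fold in HBR2340 against N2, and called 10 of 15475 unchanged genes. The changed genes were drawn from those with a mean log2 CPM of at least 1, and no library was made to stand apart as N2 B does. These rates therefore do not cover changed genes with fewer counts or the effect of such a library. In PHX2193, simulated without change, edgeR called 0 of 15705. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.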

Results

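RNA abundance was measured by sequencing in whole Caenorhabditis elegans larvae held for 48 h in developmental arrest at the first larval stage (L1), the arrest that larvae enter when they hatch without food. Eggs freed from their mothers with hypochlorite were left in M9 buffer, and RNA was extracted from the larvae after bead beating. There were 3 strains with 4 biological replicates each, called A to D. N2 is the wild type, HBR2340 is labelled with the allele syb1445 of flp-11, and PHX2193 with the allele syb2193 of the same gene. The gene flp-11 encodes FMRFamide-like neuropeptides of the sleep-active interneuron RIS. The labels do not say what either allele changes. The comparisons ask how RNA levels in arrested larvae differ between each strain and the wild type, and between both strains. Total gene counts per library ranged from 23068345 to 34832403 in N2, from 25642142 to 28865328 in HBR2340 and from 23941071 to 30526360 in PHX2193. Of 46934 genes in the table, 15908 had enough counts to be tested.

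In a principal component analysis of log2 CPM (counts scaled to the size of the library), the first component held 36.6% of the variance. Along it the 4 HBR2340 libraries lay together, away from PHX2193 and from N2 A, C and D. The library N2 B stood apart from all others, at −98.4 on the second component (26.3% of the variance). In N2 B, 3134 genes (19.7% of those tested) lay more than 2-fold from the mean of the other N2 libraries, against 3.87%, 5.15% and 7.04% for N2 A, C and D measured the same way. Genes listed as targets of the hypoxia factor HIF-1 differed there. Of these, 8 of 9 were more than 2-fold higher in N2 B than in the other N2 libraries, with a median log2 ratio of 2.53. Heat shock genes (13 of 16 more than 2-fold higher, median 1.79), glycolytic enzymes (10 of 19, median 1.79) and genes of the glyoxylate cycle, gluconeogenesis and trehalose (12 of 17, median 1.55) were also high in that library. Because these genes set the N2 mean, values without N2 B are given below for the lists whose call they change, and the named genes that gain a call without it are listed.

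**Figure D1:**
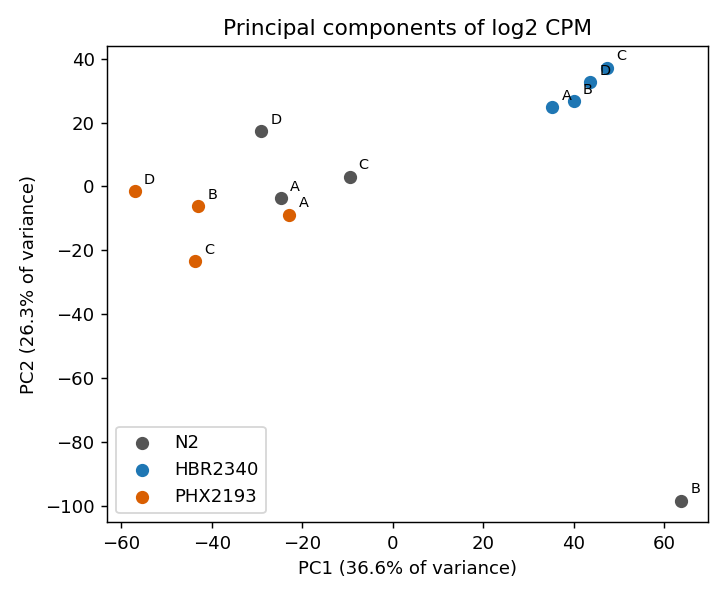
Principal components of log2 CPM for the 12 libraries; the x axis is the first component (36.6% of the variance), the y axis the second (26.3%), points are libraries coloured by strain and marked with their replicate letter. N2 B lies alone at 63.7 on the first and −98.4 on the second component.

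The labelled gene, flp-11 (WBGene00001454; WBcel235 chromosome X, 4677334 to 4678129, minus strand, protein coding), was lower in every library of both strains than in every N2 library. Its normalised level was 210.6, 367.4, 231.2 and 205.6 CPM in N2 A to D (mean 253.7 ± 76.6, SD, n = 4), 108.3, 113.0, 127.8 and 142.2 CPM in HBR2340 (122.8 ± 15.4), and 19.3, 23.2, 22.1 and 19.7 CPM in PHX2193 (21.1 ± 1.88). The log2 fold change against N2 was −1.05 ± 0.18 (SE, n = 4 per strain) in HBR2340 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00368) and −3.59 ± 0.20 in PHX2193 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.3e-06). PHX2193 was lower than HBR2340 by the same test, with a log2 fold change of −2.54 ± 0.19 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.9e-06). All 3 calls held when any 1 of the 12 libraries was left out. Without N2 B, the N2 library with the highest flp-11 level, the log2 fold change was −0.83 ± 0.10 in HBR2340, less than 2-fold. In PHX2193 it was −3.36 ± 0.11. The gene's span overlaps WBGene00019345 on the other strand, which ends at 4677350. The strandedness of the counts is not given in the sources used here.

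Among 3 potassium channel family genes named in advance beside flp-11, unc-58 (chromosome X, 10104610 to 10133182), which encodes a channel of the K2P family, rose in HBR2340 from 27.2 ± 3.07 to 61.3 ± 6.15 CPM (mean ± SD, n = 4 each), a log2 fold change of 1.17 ± 0.12 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000202). PHX2193 had 26.6 ± 3.54 CPM of unc-58, a log2 fold change of −0.03 ± 0.12 against N2 that did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.953). The K2P gene egl-23 (chromosome IV, 13989081 to 14012074) had 20.4 ± 4.85 CPM in N2, 25.99 ± 4.47 in HBR2340 and 19.97 ± 2.75 in PHX2193. Its adjusted p was 0.303 in HBR2340 and 0.969 in PHX2193 against N2 and 0.170 between both (edgeR quasi-likelihood, Benjamini-Hochberg). The K2P gene twk-18 (chromosome X, 8988128 to 8991975) had 39.0 ± 10.1, 44.0 ± 5.67 and 25.6 ± 4.04 CPM in the same order. It was lower in PHX2193 than in HBR2340 (log2 fold change −0.78 ± 0.18, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00827). Annotated genes overlap the span of unc-58 on both strands, so some of its counts are uncertain.

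**Figure D2:**
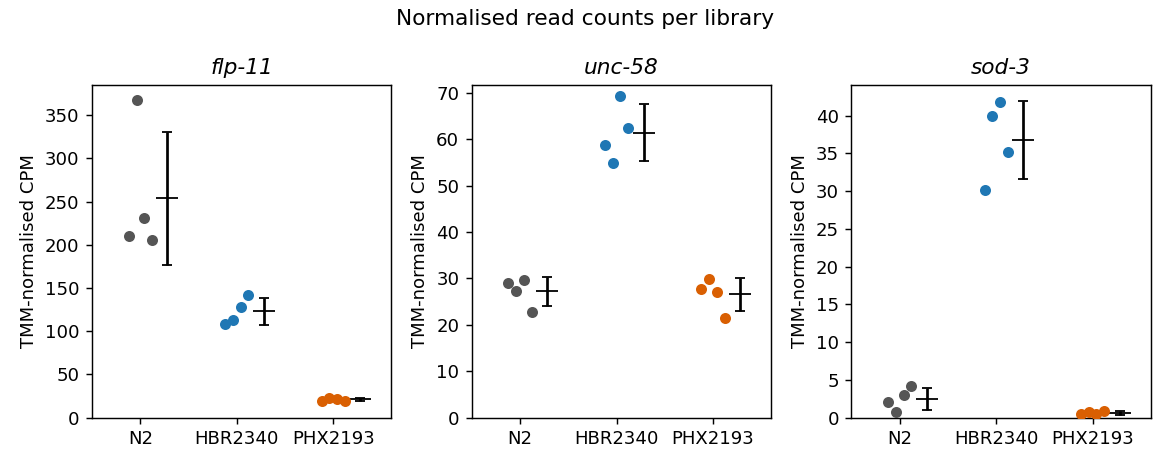
Normalised level of flp-11, unc-58 and sod-3 per library (y axis, CPM after TMM scaling; x axis, strain); points are libraries and bars the mean ± SD of 4 libraries. The flp-11 level lies between 19.3 and 23.2 CPM in PHX2193 and between 108.3 and 142.2 CPM in HBR2340, below every N2 library.

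HBR2340 against N2. Larvae of HBR2340 carried far more RNA of the superoxide dismutase genes sod-3 and sod-5 than N2 and more RNA of 10 of 15 body wall muscle genes. They carried less RNA of 8 of 24 protease genes, 20 of 150 lysozyme and lectin genes and 14 of 56 neuropeptide-like genes. These 4 lists passed the set test at a fixed correlation between genes, and none passed with an estimated correlation (camera adjusted p = 0.247, 0.312, 0.312 and 0.811). The sod-3 level (chromosome X, 17092753 to 17094306), encoding a mitochondrial manganese superoxide dismutase, rose from 2.50 ± 1.43 to 36.8 ± 5.22 CPM (log2 fold change 3.85 ± 0.37, n = 4 per strain, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000116). The sod-5 level (chromosome II, 4417633 to 4419130), encoding a copper/zinc superoxide dismutase, rose from 5.19 ± 1.53 to 188 ± 87.2 CPM (5.17 ± 0.41, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.1e-05). The RNA of cpr-2 (chromosome V, 16532936 to 16534100), a cathepsin B-like cysteine protease, fell from 1243 ± 586 to 62.2 ± 38.9 CPM (−4.32 ± 0.50, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000409).

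In total 1173 genes differed between HBR2340 and N2, 532 higher and 641 lower, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, and 587 of them changed more than 2-fold (270 higher, 317 lower). In 1065 of the 1173 genes, all 4 libraries of one strain lay above all 4 of the other; over all tested genes that share was 13.8%, where chance gives 2.86%. Besides sod-3 and sod-5, the 10 genes with the largest rises were D1086.9 (log2 fold change 6.13 ± 0.49), W03B1.3 (5.70 ± 0.39), the adenine nucleotide translocase gene ant-1.2 (5.03 ± 0.51), Y110A2AL.2 (3.96), R05D7.2 (3.63), the acyltransferase family gene oac-51 (3.63), H39E23.3 (3.45) and the tau tubulin kinase family gene ttbk-5 (3.44). D1086.9 and W03B1.3 had means of only 0.470 and 0.412 CPM in N2, near the 0.0823 to 0.170 CPM that 3 counts make in those libraries, so their folds are imprecise. The mean of ant-1.2 in N2, 0.181 CPM, was closer still to that level, so its fold is imprecise too. Besides cpr-2, the largest falls were in ZK218.3, the alcohol dehydrogenase gene adh-1 (−4.56 ± 0.94), W09C3.7 (−4.52 ± 0.66), the carboxypeptidase family gene pcp-2 (−3.56), Y46H3A.5 (−3.39), F59A6.4 (−3.29), R08F11.7 (−3.22), K08H2.5 (−3.14) and F35E8.10 (−3.08). No fold is given for ZK218.3, which had at most 0.0390 CPM in any HBR2340 library, under the level of 3 counts. Its call ended without N2 A or C or any 1 HBR2340 library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0590 to 0.0993). That of F59A6.4 ended without any 1 HBR2340 library or PHX2193 A, B or D (0.0609 to 0.1195). Some folds moved by more than 1.5 times without 1 library. Without N2 B they were −1.31 for F59A6.4, −2.98 for adh-1 and −2.72 for pcp-2. Without N2 D they were 7.05 for D1086.9 and 4.42 for oac-51, and without HBR2340 A −3.93 for F35E8.10.
The number of genes called depended on single libraries. It was 2880 without N2 B (1288 higher, 1592 lower, 1168 of them among the 1173), 774 without N2 A, and 707, 661 and 671 without HBR2340 B, C and D. Among the named genes, col-80, exc-13, odr-10, atp-3, nuo-1, hsp-70, hsp-43, cah-4, cki-1, cki-2 and WBGene00010964 gained a call without N2 B (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.000221 to 0.0407).

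Of the body wall muscle markers, 10 of 15 were higher in HBR2340 and none lower over all genes tested (12 higher and 0 lower when adjusted over the list alone). The median log2 fold change was 0.87. Examples are tnt-2, a troponin T (chromosome X, 8721546 to 8723550; 50.1 ± 12.9 to 210 ± 11.8 CPM, log2 fold change 2.07 ± 0.18), and unc-52, the basement membrane protein perlecan (chromosome II, 14647321 to 14684456; 191 ± 26.1 to 466 ± 33.7 CPM, 1.29 ± 0.15). The list passed the set test (camera, Benjamini-Hochberg adjusted p = 5.45e-16 over 42 lists) but not with an estimated correlation between genes (adjusted p = 0.247 with an estimated correlation). Markers of 4 other tissues did not pass the set test. The median was 0.08 for 19 pan-neuronal genes (0 called by edgeR, 2 at unadjusted p under 0.05, 0 by DESeq2 and by limma-voom; camera adjusted p = 0.250). It was −0.20 for 13 intestinal genes (1 lower; 0.426) and −0.06 for 17 pharynx genes (1 higher, phat-8 at 1.16 ± 0.19, and 2 lower, among them phat-6 at −1.15 ± 0.18; 1 and 3 adjusted over the list alone; 0.943). It was 0.25 for 9 epidermal genes (0 called by edgeR, 1 at unadjusted p under 0.05, 0 by DESeq2 and by limma-voom; 0.178).

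**Figure D3:**
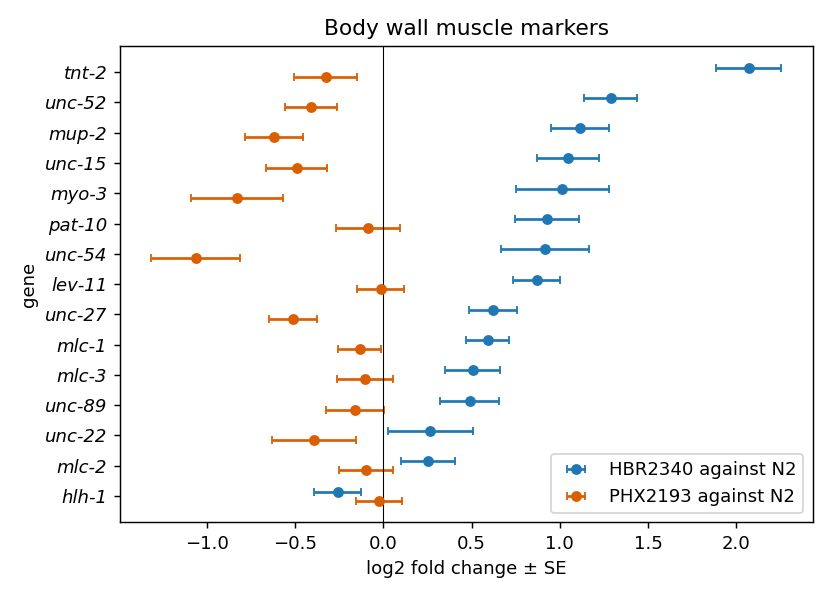
Log2 fold change against N2 (x axis, ± SE) of the 15 body wall muscle markers (y axis) in HBR2340 and PHX2193, from 4 libraries per strain. In HBR2340 the values run from −0.26 (hlh-1) to 2.07 (tnt-2), and 10 markers are higher; in PHX2193 no marker passed the test with all libraries.

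Of 14 genes listed as raised by the FOXO factor DAF-16, 4 were higher in HBR2340 and 1 lower (4 and 2 adjusted over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 7.2e-05). It was the one list of the 12 passing that held with an estimated correlation (adjusted p = 0.0418 with an estimated correlation; 0.0548 without N2 B). The 4 higher genes were sod-3, sod-5, lea-1 (1.75), a late embryogenesis abundant protein, and mtl-1 (1.01), a metallothionein. The lower one was dod-6 (−0.88). Of these, lea-1, mtl-1 and dod-6 were picked after their values were seen. Protein genes of the mitochondrial genome had a median of 0.92 (camera adjusted p = 1.5e-06; adjusted p = 0.811 with an estimated correlation), but 1 of 12 passed over all genes, WBGene00010967 (0.78 ± 0.19), and 7 were higher when adjusted over the list alone. The call of WBGene00010967 ended without N2 A or D or any 1 HBR2340 library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0526 to 0.0707). Antimicrobial peptide genes were higher in 2 of 16 (4 higher and 1 lower adjusted over the list alone), cnc-11 (2.16 ± 0.19) and nlp-28 (1.39 ± 0.21). K2P channel genes were higher in 4 of 45 and lower in 2 (7 and 2 adjusted over the list alone), among them unc-58 and, lower, twk-22 (−1.83 ± 0.33). Both lists passed (camera adjusted p = 0.0302 and 0.0147; adjusted p = 0.811 with an estimated correlation for each). The antimicrobial list did not pass without N2 B (0.186), N2 C (0.0789) or HBR2340 A (0.0791). The K2P list did not pass without N2 B (0.211), N2 D (0.0698) or HBR2340 C (0.0547). In N2 B the medians of the same lists lay at −0.51 and −0.38 against the other N2 libraries. Ciliated neuron markers passed with a median of 0.22 (camera adjusted p = 0.0457; adjusted p = 0.811 with an estimated correlation). None was called by edgeR (0 of 20, 5 at unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom), with odr-10 at −0.45 (called without N2 B, edgeR adjusted p = 0.0189) and che-2 at 0.37. The list did not pass without N2 B (0.282), N2 D (0.125), HBR2340 C (0.123), HBR2340 D (0.0717), PHX2193 A (0.0504) or PHX2193 C (0.0531).

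Of 56 neuropeptide-like protein genes, 14 were lower in HBR2340 and 1 higher (17 and 1 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 9.4e-05; adjusted p = 0.811 with an estimated correlation). The list was led by nlp-66 (−1.72 ± 0.21), while nlp-71 rose (1.06 ± 0.13). FMRFamide-like peptide genes other than flp-11 had 3 of 29 lower, flp-10 (−0.83 ± 0.11) and flp-28 (−0.40 ± 0.08) among them (4 adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.811 with an estimated correlation). This list did not pass without N2 C (0.154), HBR2340 A (0.0791) or HBR2340 B (0.0800). Lysozyme, saposin, infection response and C-type lectin genes had 20 of 150 lower and 2 higher (34 and 4 adjusted over the list alone; median −0.39, camera adjusted p = 7.7e-05, adjusted p = 0.312 with an estimated correlation). The lectin gene clec-24 fell (−2.47 ± 0.35) and the lysozyme gene ilys-4 rose (1.86 ± 0.21). Aspartyl and cathepsin protease genes had 8 of 24 lower and none higher (10 adjusted over the list alone; median −0.51, camera adjusted p = 7.2e-05, adjusted p = 0.312 with an estimated correlation), among them cpr-2 and cpr-5 (−1.25 ± 0.22). Lipase and fatty acid oxidation genes had 2 of 33 lower, fil-1 (−1.65 ± 0.23) and lipl-8 (−2.21 ± 0.41; 4 lower adjusted over the list alone). Histone genes had 1 of 25 lower, his-72 (−0.62 ± 0.11; 1 adjusted over the list alone). Both lists passed at a camera adjusted p of 0.0457 (adjusted p = 0.811 with an estimated correlation) and did not pass without N2 B (0.339 and 0.701). The lipid call also ended without HBR2340 C (0.123), HBR2340 D (0.108), PHX2193 C (0.0512) and PHX2193 D (0.0534). The histone call also ended without HBR2340 A (0.0791), B (0.0683) and D (0.0671), PHX2193 C (0.0531) and PHX2193 D (0.0553).

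The remaining lists did not pass the set test in HBR2340 against N2. Cytochrome P450, glucuronosyltransferase and glutathione S-transferase genes had 16 of 157 higher and 7 lower (17 and 9 adjusted over the list alone; camera adjusted p = 0.0653), including cyp-33C1 (2.74 ± 0.23) and cyp-33C2 (2.87 ± 0.28). Cuticle collagens had 3 higher, col-50 (2.68 ± 0.44) and col-142 (1.93 ± 0.33) among them, 4 lower and 101 not passing (3 and 3 adjusted over the list alone; 0.213). Without N2 B the collagens had 17 higher and 7 lower and passed (0.0361; adjusted p = 0.920 with an estimated correlation). Insulin-like peptide genes had ins-10 higher (1.18 ± 0.16) and daf-28 lower (−1.03 ± 0.27) of 24 (3 and 4 adjusted over the list alone; 0.426). Glyoxylate, gluconeogenesis and trehalose genes had the trehalase genes tre-4 higher (0.76 ± 0.13) and tre-5 lower (−1.58 ± 0.16) of 17 (2 and 7 adjusted over the list alone; 0.129). Glycolysis had the hexokinase genes hxk-2 higher (0.41 ± 0.10) and hxk-1 lower (−1.16 ± 0.18) of 19 (0.211). Glutathione and oxidative stress genes linked to SKN-1 had gst-10 higher (1.26 ± 0.25) of 16 (0.219). Endoplasmic reticulum stress genes had dnj-27 lower (−0.64 ± 0.15) of 14 (0.0994). Insulin and growth signalling genes had akt-1 (0.47 ± 0.11) and pdk-1 (0.81 ± 0.20) higher and 1 lower of 22 (0.219). Moulting factors had bli-3 lower (−0.50 ± 0.14) of 22 (0.742). Yolk protein genes vit-3 (−1.01 ± 0.25) and vit-6 (−2.07 ± 0.58) were lower, 2 of 3 (0.129; without N2 B 0.0117, and 0.342 with an estimated correlation). So were the sperm gene ssp-33 (−2.33 ± 0.63, and −3.02 without HBR2340 A), 1 of 5 (2 adjusted over the list alone; 0.213), and the intestinal factor elt-2 (−0.91 ± 0.21). The calls of daf-28, hxk-2, dnj-27, akt-1, pdk-1, bli-3, vit-3, vit-6, ssp-33 and elt-2 each ended in 3 or more leave-outs, N2 A, C or D or HBR2340 libraries among them. The edgeR quasi-likelihood Benjamini-Hochberg adjusted p reached 0.107, 0.0847, 0.0659, 0.0791, 0.0851, 0.0944, 0.0891, 0.133, 0.123 and 0.0657 in that order.

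The other lists gave these medians in HBR2340 against N2, none past the set test with all libraries. HIF-1 targets stood at −0.69 (camera adjusted p = 0.219), heat shock genes at −0.96 (0.373), fatty acid synthesis genes at −0.36 (0.154) and the gpd-2 operon at −0.84 (0.632). Their medians in N2 B lay 2.53, 1.79, 1.13 and 2.99 above the other N2 libraries. Without N2 B all 4 turned positive, at 0.33 (0.339), 0.14 (0.0795), 0.05 (0.756) and 0.61, where the gpd-2 operon passed (0.0480; adjusted p = 0.920 with an estimated correlation). The medians of the glyoxylate list (−0.78) and of glycolysis (−0.61) turned to 0.19 (0.594) and 0.16 (0.291). Genes listed as lowered by DAF-16 stood at −0.73 (0.154; without N2 B 0.0361, and 0.758 with an estimated correlation). Nuclear respiratory chain genes stood at −0.11 (0.622), and at 0.18 without N2 B, where 4 of 29 were higher and 1 lower and the list passed (0.00641; adjusted p = 0.920 with an estimated correlation). Cytosolic ribosomal protein genes stood at −0.03 (0.622), ribosomal RNA at −0.77 (0.373), autophagy and lysosome genes at −0.20 (0.213) and mitochondrial stress genes at 0.01 (0.742). Cell cycle genes stood at −0.40 (0.236), germ cell markers at −0.44 (0.494) and embryo or oocyte markers at −0.70 (0.742). The list of flp-11 and its channel genes, of which 1 rose and 1 fell, did not pass as a whole (0.219).

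PHX2193 against N2. Larvae of PHX2193, the strain with the lowest flp-11 level, differed from N2 in few single genes. Apart from flp-11, the clearest change was the near loss of srw-85 (chromosome V, 19429387 to 19431136), a gene of a chemoreceptor family, from 67.3 ± 9.18 to 1.84 ± 0.814 CPM (log2 fold change −5.17 ± 0.26, n = 4 per strain, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.0e-06). The lysozyme gene lys-1 (chromosome V, 10277904 to 10279056) fell from 26.8 ± 4.47 to 10.003 ± 1.78 CPM (−1.42 ± 0.15, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00281). Rises were seen in srlf-29 (0.608 ± 0.152 to 11.5 ± 4.36 CPM, 4.25 ± 0.52, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00513) and W06F12.3 (13.2 ± 1.89 to 35.8 ± 7.66 CPM, 1.45 ± 0.17, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00445).

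In total 58 genes differed, 26 higher and 32 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05; 1845 at unadjusted p under 0.05), and 35 changed more than 2-fold (19 higher, 16 lower); in all 58 the 4 libraries of one strain lay above the 4 of the other. The other named rises were ZK218.5 (2.996 ± 0.55), ZK218.1 (2.65 ± 0.41), the cytochrome P450 gene cyp-13A8 (2.197 ± 0.38), R08F11.7 (1.89), the collagen gene col-138 (1.87), C12D5.3 (1.73), rml-4 (1.73) and the chemoreceptor gene srw-68 (1.47). The other named falls were the collagen gene col-80 (−3.67 ± 0.61, and −2.69 without N2 B), F55G11.8 (−2.71), F08H9.4 (−1.95), exc-13 (−1.72), the insulin-like peptide gene ins-24 (−1.67), R09D1.12 (−1.66), the lysozyme gene ilys-4 (−1.26) and the saposin-like gene spp-24 (−1.08). Of the 21 named genes called, 5 kept their call whichever library was left out. They were flp-11, srw-85, lys-1, srlf-29 and W06F12.3, with highest adjusted p of 3.9e-05, 3.0e-05, 0.0178, 0.0388 and 0.0354 (edgeR quasi-likelihood, Benjamini-Hochberg). The other 16 each lost it without N2 C and without PHX2193 C, among other libraries, with a highest adjusted p of 0.0748 to 0.147 (edgeR quasi-likelihood, Benjamini-Hochberg).
The count rested on single libraries. It was 228 without N2 B (120 higher, all 58 among them), 9 without N2 C and 37 without N2 D. It was 10, 7 and 8 without PHX2193 B, C and D, and 31, 29, 38 and 23 without HBR2340 A to D, which enter the filter, the scaling and the estimate of the spread. DESeq2 called 451 genes, while edgeR called 24 with a replicate block, 4 without the D libraries of N2 and PHX2193, and 3 with only the 8 libraries compared. Among the named genes, Y110A2AL.2, sod-3, mtl-1, tre-5, tnt-2, vit-6, scl-14, C09F12.2, col-98, col-181 and cki-1 gained a call without N2 B (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00411 to 0.0487).

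Several lists passed the set test in PHX2193 with few or no called genes. Body wall muscle markers were lower (median −0.33, camera adjusted p = 2.0e-05; adjusted p = 0.964 with an estimated correlation). Of 15, edgeR called 0 (6 at unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom), and 6 were lower adjusted over the list alone. Without N2 B, tnt-2 was called (−0.50, edgeR adjusted p = 0.0440). The myosin gene unc-54 stood at −1.06 ± 0.25 and the troponin I gene unc-27 at −0.51 ± 0.13. DAF-16 raised genes were lower (median −0.59, camera adjusted p = 0.0218; adjusted p = 0.291 with an estimated correlation; 0.0639 without N2 D). Of 14, edgeR called 0 (7 at unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom), and 5 were lower and 1 higher adjusted over the list alone. Here sod-3 stood at −1.99 ± 0.40 and mtl-1 at −0.81 ± 0.17. Both passed without N2 B (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00411 and 0.0487), mtl-1 also without PHX2193 A (0.0113). Nuclear genes of the respiratory chain (median −0.44, camera adjusted p = 4.0e-07) and cytosolic ribosomal protein genes (median −0.16, camera adjusted p = 1.5e-06) were lower. In these lists edgeR called 0 of 29 and 0 of 80 (10 and 1 at unadjusted p under 0.05, 0 and 0 by DESeq2 and by limma-voom), with atp-3 at −0.58 and rpl-37 at −0.34. Both lists gave an adjusted p = 0.964 with an estimated correlation. In N2 B the respiratory chain genes had a median log2 ratio of 0.93 to the other N2 libraries, and without that library the median in PHX2193 was −0.07 (camera adjusted p = 0.0219). Yolk protein genes were higher (median 1.14, camera adjusted p = 0.0121; adjusted p = 0.738 with an estimated correlation). Of 3, edgeR called 0 (1 at unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; 1 higher adjusted over the list alone), with vit-6 at 1.67 ± 0.53 (called without N2 B, edgeR adjusted p = 0.0210) and vit-2 at 1.14 ± 0.53. The list of flp-11 and the 3 channels named beside it passed (camera adjusted p = 1.8e-11) with 1 called gene, flp-11 itself (2 adjusted over the list alone), while unc-58 stood at −0.03. This list alone held with an estimated correlation (adjusted p = 0.0303 with an estimated correlation). As flp-11 is the labelled gene and the one called member, that pass adds little to the fall of flp-11 itself.

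Further lists passed with all libraries but lost the call without single ones. Heat shock genes (median −0.56, camera adjusted p = 0.0157; hsp-16.2 at −2.39 ± 0.80 and hsp-16.41 at −2.35 ± 0.79) gave 0.639 without N2 B and 0.128 without PHX2193 A. Without N2 B the median was −0.05, hsp-16.2 −0.36 ± 0.22 and hsp-16.41 −0.40 ± 0.25, so most of these falls came from that 1 library. Glycolytic enzymes (median −0.66, camera adjusted p = 0.00195; aldo-1 at −1.54 and enol-1 at −1.45) gave 0.797 without N2 B, where the median was −0.01 and both genes were at −0.04, so these falls came from N2 B. Each list had 0 genes called by edgeR (6 of 16 and 4 of 19 at unadjusted p under 0.05, 1 and 0 by DESeq2, 0 and 0 by limma-voom). SKN-1 linked genes (median −0.14, camera adjusted p = 0.0348; sod-1 at −0.30, prdx-2 at −0.49) gave 0.0687 without N2 A, 0.111 without N2 C and 0.304 without PHX2193 C. Antimicrobial peptide genes (median −0.18, camera adjusted p = 0.0490; nlp-28 at −0.77, cnc-11 at −0.62; 2 lower adjusted over the list alone) gave 0.0659 without N2 A, 0.448 without N2 D, 0.0878, 0.0796, 0.0818 and 0.0838 without HBR2340 A to D, 0.352 without PHX2193 A and 0.506 without PHX2193 C. Among the SKN-1 linked and the antimicrobial genes, edgeR called 0 of 16 each (2 and 5 at unadjusted p under 0.05, 1 and 1 by DESeq2, 0 and 0 by limma-voom). All 4 lists gave an adjusted p = 0.964 with an estimated correlation, as did ribosomal RNA (median −1.15, camera adjusted p = 0.0348). Of 4 ribosomal RNA genes, 0 were called by edgeR, by DESeq2 or by limma-voom and 0 had an unadjusted p under 0.05, with rrn-2.1 at −1.33. The list gave 0.143, 0.117 and 0.103 without N2 A, B and D and 0.211, 0.0989 and 0.0564 without PHX2193 A, B and D. Ribosomal RNA took 5.39 ± 3.08% of the counts in N2, 3.16 ± 2.23% in HBR2340 and 2.81 ± 3.50% in PHX2193 (mean ± SD, n = 4).

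No other list passed in PHX2193 against N2 with all libraries. Without N2 B, 5 more passed: autophagy and lysosome genes (median 0.10, camera adjusted p = 0.00448), endoplasmic reticulum stress genes (0.11, 0.0164), pharynx markers (0.16, 0.0164), the P450 and conjugation families (−0.11, 0.0242) and histones (0.22, 0.0319). With an estimated correlation these gave an adjusted p of 0.433, 0.845, 0.936, 0.944 and 0.608. HIF-1 targets had a median of −1.55 (camera adjusted p = 0.106) and the gpd-2 operon −1.43 (0.106). Glyoxylate, gluconeogenesis and trehalose genes stood at −0.68 (0.121) and fatty acid synthesis genes at −0.68 (0.0548). The medians of these lists in N2 B lay 2.53, 2.99, 1.55 and 1.13 above the other N2 libraries, and without N2 B they stood at 0.14, 0.02, 0.11 and 0.01. Lysozyme and lectin genes had 3 of 150 lower (4 higher and 6 lower adjusted over the list alone; 0.537). Collagens had 1 higher, 1 lower and 106 not passing (2 and 8 adjusted over the list alone; 0.106). Insulin-like peptide genes had 1 of 24 lower (1 and 4 adjusted over the list alone; 0.924), and the P450 and conjugation families 1 of 157 higher (1 and 1 adjusted over the list alone; 0.541). Neuropeptide-like genes had a median of −0.03 (0.916) and the FMRFamide-like genes 0.02 (0.916). Pan-neuronal, intestinal, pharyngeal and epidermal markers had medians of −0.04 (0.916), 0.02 (0.916), 0.17 (0.141) and 0.08 (0.924). Protease genes stood at −0.11 (0.338), K2P genes at −0.03 (0.916), mitochondrially encoded genes at 0.01 (0.916) and histones at −0.08 (0.924). The remaining lists, with camera adjusted p of 0.581 to 0.924, had medians between −0.32 (embryo or oocyte markers) and 0.04 (genes listed as lowered by DAF-16).

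PHX2193 against HBR2340. Compared directly, PHX2193 had less RNA of sod-3, sod-5, unc-58 and 12 of 15 body wall muscle genes than HBR2340. It had more RNA of cpr-2, of 2 of 3 yolk genes and of 39 of 150 lysozyme and lectin genes, of which 12 were lower. None of these 3 lists passed with an estimated correlation (camera adjusted p = 0.107, 0.715 and 0.914), and the lysozyme and lectin list also lost its call without N2 B, HBR2340 C or PHX2193 C. This comparison also tests whether both strains' changes against N2 differ. The largest falls were in D1086.9 (34.8 ± 8.51 to 0.0669 ± 0.0656 CPM, a mean under the 0.0892 to 0.126 CPM that 3 counts make in the PHX2193 libraries, so no fold is given), W03B1.3 (log2 fold change −6.81 ± 0.42), sod-5 (−6.44 ± 0.44), H39E23.3 (−6.08, and −6.84 without PHX2193 A), sod-3 (−5.83 ± 0.42), Y110A2AL.2 (−5.51), srw-85 (−5.41), ant-1.2 (−5.28), F08H9.4 (−4.998) and the thaumatin family gene thn-1 (−4.32, and −5.06 without PHX2193 A). The folds of W03B1.3, H39E23.3 and ant-1.2 are imprecise, with 0.192, 0.194 and 0.156 CPM in PHX2193. The largest rises were in ZK218.3 (0.0273 ± 0.0183 to 7.005 ± 4.80 CPM, the former under the level of 3 counts), srlf-29 (5.73 ± 0.58, and 6.34 without HBR2340 C), W09C3.7 (5.72 ± 0.68), ZK218.1 (5.46), R08F11.7 (5.10 ± 0.35), scl-14 (5.05), Y62F5A.10 (4.78), C09F12.2 (4.71), the chemoreceptor gene sri-4 (4.66) and K08H2.5 (4.66).

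In total 3106 genes differed, 1612 higher and 1494 lower in PHX2193 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 1595 changed more than 2-fold (882 higher, 713 lower). Of the 3106, 1091 and 58 were themselves called in HBR2340 and PHX2193 against N2.
Without N2 B, which is in neither strain compared but enters the filter, the scaling and the estimate of the spread, the count was 5339 (2808 higher, 2531 lower, all 3106 among them). Among the named genes, F59A6.4, che-2, hsp-16.2, hsp-16.41, prdx-2, rpl-41.1, cox-5B, vit-2 and WBGene00010967 gained a call without it (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00109 to 0.0383).

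Body wall muscle genes were lower in PHX2193 in 12 of 15, with none higher (14 adjusted over the list alone; median −1.01, camera adjusted p = 1.5e-16; adjusted p = 0.107 with an estimated correlation). The falls were led by tnt-2 (−2.40 ± 0.19) and unc-52 (−1.70 ± 0.15). DAF-16 raised genes were lower in 6 of 14 and higher in 1 (6 and 2 adjusted over the list alone; median −0.47, camera adjusted p = 0.000184; adjusted p = 0.0517 with an estimated correlation). Of flp-11 and the 3 channel genes, 3 were lower (flp-11, unc-58 at −1.21 ± 0.12 and twk-18; camera adjusted p = 1.9e-06, adjusted p = 0.0981 with an estimated correlation). Mitochondrially encoded genes were lower in 2 of 12, WBGene00010964 (−0.66 ± 0.16) and WBGene00000829 (−1.04 ± 0.30), and in 7 adjusted over the list alone (camera adjusted p = 0.00167). The call of WBGene00000829 ended without any 1 HBR2340 library or PHX2193 C (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0503 to 0.0721). Antimicrobial peptide genes were lower in 6 of 16 and higher in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00970), with cnc-11 at −2.78 ± 0.20 and nlp-28 at −2.17 ± 0.22. Neuropeptide-like genes were higher in 15 of 56 and lower in 3 (17 and 3 adjusted over the list alone; median 0.16, camera adjusted p = 0.0155), such as nlp-66 (1.83 ± 0.21) and nlp-64 (0.96 ± 0.13). Yolk genes were higher in 2 of 3, vit-3 (1.31 ± 0.25) and vit-6 (3.74 ± 0.59), and in 3 adjusted over the list alone (camera adjusted p = 0.0155; adjusted p = 0.715 with an estimated correlation). With an estimated correlation the mitochondrial, antimicrobial and neuropeptide lists each gave an adjusted p of 0.914.

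A further 5 lists passed this comparison at camera adjusted p = 0.0409 each (adjusted p = 0.914 with an estimated correlation). Lysozyme and lectin genes were higher in 39 of 150 and lower in 12 (44 and 16 adjusted over the list alone), with clec-24 at 3.93 ± 0.35 and ilys-4 at −3.12 ± 0.23. They did not pass without N2 B (0.0534), HBR2340 C (0.154) or PHX2193 C (0.0516). Proteases were higher in 7 of 24 and lower in 3 (8 and 3 adjusted over the list alone), with cpr-2 at 4.31 ± 0.50 and asp-12 at 1.07 ± 0.15. They did not pass without N2 B (0.0625), HBR2340 C (0.158) or PHX2193 C (0.0512). K2P channels were lower in 9 of 45 and higher in 3 (the same numbers adjusted over the list alone), with twk-21 at 2.92 ± 0.48. That list did not pass without N2 B (0.0534), HBR2340 C (0.113), PHX2193 C (0.0516) or PHX2193 D (0.0988). SKN-1 linked genes were lower in 4 of 16, among them gst-10 (−1.67 ± 0.26) and sod-1 (−0.50 ± 0.09; 4 adjusted over the list alone). That call ended without N2 B (0.0534), N2 D (0.0506), HBR2340 B (0.0807) or PHX2193 C (0.117). Nuclear respiratory chain genes were lower in 2 of 29, atp-3 (−0.72 ± 0.20) and nuo-1 (−0.60 ± 0.20), with 0 adjusted over the list alone by edgeR (8 at unadjusted p under 0.05, 4 by DESeq2, 3 by limma-voom over all genes). That list did not pass without HBR2340 B (0.0575) or PHX2193 D (0.0932). The calls of atp-3 and nuo-1 also ended in 5 and 9 leave-outs, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p of up to 0.0716 and 0.134, each without PHX2193 D.

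Lists that did not pass the set test here still held called genes. Over all 15908 tested genes, 1612 were higher and 1494 lower (19.5% called), so a list with counts near these shares is not set apart from other genes. Collagens had 22 lower, 6 higher and 80 not passing (23 and 6 adjusted over the list alone; camera adjusted p = 0.0758, and without N2 B 0.0336, with 26 lower and 14 higher, and 0.833 with an estimated correlation), with col-98 at −3.49 ± 0.40 and col-181 at 1.56 ± 0.20. The P450 and conjugation families were lower in 32 of 157 and higher in 14 (34 and 16 adjusted over the list alone; 0.0623). Pharynx genes were higher in 6 of 17 and lower in 1 (7 and 2 adjusted over the list alone; 0.466), with phat-6 at 1.33 ± 0.18 and phat-8 at −1.63 ± 0.19. Lipid catabolism genes were higher in 6 of 33 (0.116). Insulin-like peptide genes were higher in 4 and lower in 5 of 24 (7 and 5 adjusted over the list alone; 0.589), with ins-10 at −1.43 ± 0.16 and ins-26 at −1.93 ± 0.30. FMRFamide-like genes were higher in 3 of 29 (0.0828), histones in 3 of 25 (0.167) and cell cycle genes in 3 of 27 (0.414). Of the last, cki-1 (1.24 ± 0.18) and cki-2 (0.65 ± 0.16) encode inhibitors of cyclin-dependent kinases. Genes of RIS and GABA neurons had 1 of 9 lower, unc-46 (−0.55 ± 0.16; camera adjusted p = 0.553). None was called by edgeR in either strain against N2 (0 at unadjusted p under 0.05, 0 by DESeq2 and by limma-voom), with medians of 0.05 and 0.003. The call of unc-46 ended without HBR2340 B, C or D or PHX2193 A, C or D (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0759 to 0.0974). Ribosomal protein genes stood at −0.14 (camera adjusted p = 0.0501), ciliated neuron markers at −0.29 (0.130) and pan-neuronal markers at −0.14 (0.368). The remaining lists had camera adjusted p of 0.343 to 0.998.

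Most genes called in both strains against N2 changed in opposite directions. Of the 34 genes called in both, 33 had opposite signs, and the single gene with the same sign was flp-11. In 21 genes the level was higher in HBR2340 and lower in PHX2193, among them ilys-4, F08H9.4, R09D1.12 and the transthyretin-related genes ttr-24, ttr-25 and ttr-47. In 12 it was lower in HBR2340 and higher in PHX2193, among them R08F11.7, ZK218.1, cyp-13A8, rml-4 and W06F12.3; the ttr genes were picked after their values were seen. Independent lists of the same sizes would share 2.12 genes with opposite and 2.16 with the same sign. Unchanged groups were simulated 100 times against the same N2 libraries. There edgeR called at most 0 genes with opposite and 1 with the same sign (mean 0.02), too few to show a sign. Across genes, which are not independent replicates, the correlation of both sets of fold changes was −0.019. Unchanged groups gave 0.505 (0.478 to 0.529) because they share the N2 libraries, so error of shared libraries favours the same sign. The covariance was −0.0058 against 0.0613 simulated, a difference of −0.0671. The simulation gave all strains the same spread, while the N2 libraries varied more than those of the other strains. The simulated error of shared libraries may thus be too small, and the difference is not a full correction for it. When the N2 libraries were split 2 and 2, so that each strain had its own controls, the correlation was −0.35 to −0.49 over the 6 splits, and 0 to 158 genes had opposite and 1 to 2 the same sign. Without N2 B, 141 genes had opposite and 11 the same sign (20.3 and 20.1 for independent lists), and the correlation was −0.17.

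**Figure D4:**
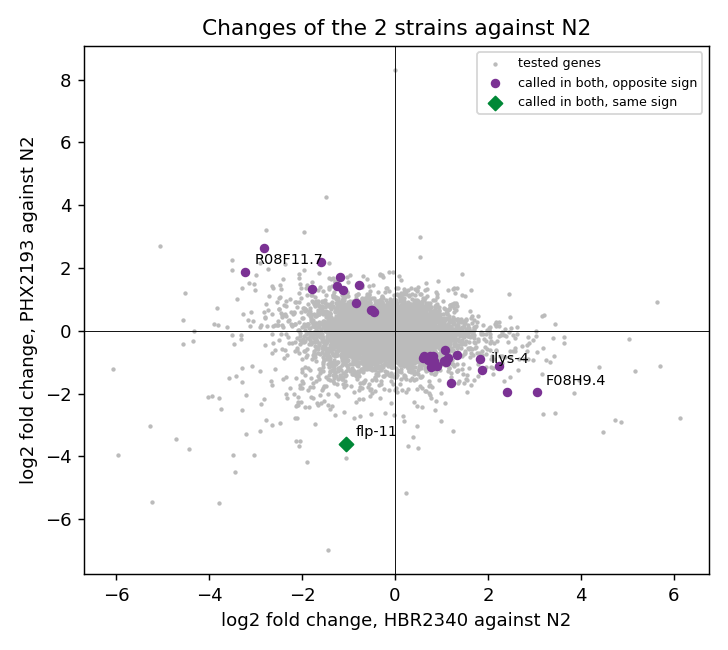
Log2 fold change of the 15908 tested genes in HBR2340 (x axis) and PHX2193 (y axis) against the same 4 N2 libraries; purple points are the 33 genes called in both strains with opposite sign and the green diamond is flp-11, the 1 gene called in both with the same sign. The purple points fill the quadrants of opposite change.

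Some of the named genes have near copies or close neighbours among which counts may be divided: cyp-33C1 and cyp-33C2 lie side by side on chromosome V, as do ZK218.1, ZK218.3 and ZK218.5, and D1086.9 and H39E23.3; W03B1.3 and oac-51 are neighbours on chromosome IV. How reads that map to several places were counted is not given in the sources used here, so the split of counts within such families, the histones, collagens and yolk genes included, is uncertain.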

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

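The test of overlapping genes at unc-58 was planned. The tests of N2 B, of the opposite changes, of neuronal markers and of extra unc-58 sequence, and the splits of the libraries, were chosen after the results were seen.

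N2 B lay apart from the other N2 libraries in 9 of the 24 values listed here, 5 gene lists and 4 genes. The tables argue against a carry-over of ribosomal RNA, whose share in N2 B was 5.78%, inside the range of the other libraries (0.437 to 8.62%). They also argue against a swap with a library of HBR2340 or PHX2193, since N2 B had 367 CPM of flp-11 against 19.3 to 142 CPM in those strains. A candidate explanation is a low-oxygen response of the larvae in that library. The 9 HIF-1 targets had a median log2 ratio of 2.53 to the other N2 libraries, above all 10000 random lists of like expression (percentile 100). Random lists were drawn for this list alone, after the results were seen, so the percentile does not single out low oxygen. The gpd-2 operon had a higher median (2.99). Those of heat shock genes (1.79), glycolytic enzymes (1.79) and fatty acid synthesis genes (1.13) were also high, and that of embryo or oocyte markers was low (−0.93). Other causes stay open and were not tested.

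The changes of HBR2340 and PHX2193 against N2 had opposite signs in 33 genes, and 3106 genes differed between both strains in the test of that difference. Error of the shared N2 libraries is argued against as a source of the opposite signs. Unchanged groups that share them gave a correlation of 0.505 (0.478 to 0.529), which favours the same sign. With 2 N2 libraries for each strain, so that no N2 library was shared, the correlation stayed under 0 in all 6 splits (−0.49 to −0.35). N2 D and PHX2193 D deviated alike (r = 0.66), so these splits may still hold error common to libraries of different strains. The amount of flp-11 RNA, lower in both strains, is argued against as what alone set the direction, since 1 of 34 genes called in both changed with the same sign. That holds only if a smaller and a larger fall of flp-11 act in the same direction, which was not tested. A larger share of muscle RNA in HBR2340 stays open for the 21 genes that rose (median 1.06, called muscle markers 0.59 to 2.07). These genes and markers were both chosen as called higher in HBR2340, so the comparison could hardly have come out otherwise and decides nothing. For genes that fell, the test used the 26 genes called higher in PHX2193, of which 12 were called lower in HBR2340. By the bound used, a larger muscle share is argued against there as the whole cause, since it would lower other tissues alike. The 26 genes called higher in PHX2193 had a median of −0.60 in HBR2340 (95% interval −1.11 to −0.28). This lay below the medians of all genes (−0.04) and of neuronal (0.08), pharynx (−0.06), epidermal (0.25) and intestinal markers (−0.20). Markers of germ cells and of embryo or oocyte had medians inside that interval, so not every marker list lay above it. The bound for that test was set after its value was seen, and an earlier bound left this cause open with the same values. The interval also treats genes as independent, which genes regulated together are not. What either allele changes in the gene stays open as well, since the labels do not give it.

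The counts of unc-58 rose in HBR2340, by 1.17 on the log2 scale. A general rise of neuronal transcripts is argued against by the pan-neuronal markers, whose median was 0.0775 (lowest −0.38, highest 0.45). Reads of an overlapping gene stay open: of 19 annotated genes that overlap unc-58, edgeR called 0, but 18 had too few counts to be tested, so the planned test could hardly have come out otherwise. Extra unc-58 sequence carried by the allele is a possible explanation that cannot be told apart from a rise of the gene itself (1.17 over the whole gene), because the table holds no counts per exon.

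Of 294 groups of 4 libraries examined, 24 had a library far from the other 3 by Dixon's ratio, where chance gives about 1 in 20 (14.7). In N2 B, the mean log2 CPM was the highest for HIF-1 targets (7.18), autophagy genes (7.12), glycolysis (7.79) and the gpd-2 operon (10.5), and the lowest for P450 and conjugation families (2.24). N2 B was also the highest in CPM for flp-11 (367), F59A6.4 (21.3) and col-80 (82.2) and the lowest for scl-14 (0.795). N2 D was the highest for cell cycle genes (4.12, mean log2 CPM) and D1086.9 (1.13 CPM), N2 A the highest for pharynx markers (6.54) and N2 C the lowest for ribosomal RNA (6.60). HBR2340 A was the highest for F35E8.10 (2.86 CPM) and the lowest for Y62F5A.10 (1.115 CPM), and HBR2340 C the lowest for R09D1.12 (6.90 CPM). HBR2340 D was the lowest for cyp-13A8 (0.284 CPM) and for ZK218.3 (0 counts, where 3 counts would be 0.122 CPM). PHX2193 A was the highest for mitochondrial stress genes (5.95) and thn-1 (3.41 CPM), and PHX2193 D the lowest for mitochondrially encoded genes (6.27). PHX2193 C was the highest for glycolysis (6.47), F59A6.4 (5.53 CPM) and the share of its counts in the 10 most abundant genes, 14.1% (95% Wilson interval 14.05 to 14.08%).

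The change against N2 differed between the strains for the following genes, with PHX2193 minus HBR2340 in log2 units as tested by edgeR. The difference was positive for ZK218.3 (7.76, a fitted value that depends on the prior count), srlf-29 (5.73), W09C3.7 (5.72), ZK218.1 (5.46), R08F11.7 (5.10), scl-14 (5.05), Y62F5A.10 (4.78), C09F12.2 (4.71), sri-4 (4.66) and K08H2.5 (4.66). It was negative for D1086.9 (−8.91, likewise a fitted value), W03B1.3 (−6.81), sod-5 (−6.44), H39E23.3 (−6.08), sod-3 (−5.83), Y110A2AL.2 (−5.51), srw-85 (−5.41), ant-1.2 (−5.28), F08H9.4 (−4.998) and thn-1 (−4.32).

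The splits ask only whether strain makes any difference to the 3 gene counts. In each comparison 1 of 35 splits of the 8 libraries compared, the real one, gave as many genes. That is the smallest share these splits can give. The labelled gene flp-11 was itself called in each comparison with all 12 libraries, so the splits cannot show whether the other calls are chance. The real counts were 1173, 58 and 3106, and the highest of the other splits were 0, 3 and 0. Fitted with the 8 libraries alone, 1 of 35 splits also gave as many genes in each comparison (627, 3 and 5316, highest other 0 in each), so for PHX2193 that rests on 3 genes. The other splits hold the strain difference in their spread, which lowers their counts. For changes over 2-fold, 1 of 35 splits again gave as many genes, with 587, 35 and 1595 genes against 0, 3 and 0.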

How the results depend on the processing

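The alternatives with sample quality weights and with the D libraries or N2 B and the D libraries removed were chosen after the results were seen. Leaving N2 B out was planned for the gene counts and added after seeing the data for the comparison of both strains and for the lists with an estimated correlation. Over all alternatives, 95 gene counts stayed within 1.5 times the reported one and 49 moved further. For named genes 4170 results were the same, 372 weaker, 30 stronger and 4 reversed, and for lists 681 were the same, 122 weaker and 2 reversed. Where a value moved, the cause was not tested, except that leaving out libraries lowers the number of samples. Depth limits genes near 3 counts, such as D1086.9 and ZK218.3.

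HBR2340 against N2 (1173 genes, 587 over 2-fold) gave 1856 genes with DESeq2, 627 (363 over 2-fold) with only the 8 libraries compared, 3515 (1099) with limma-voom and sample quality weights, and 3035 (1064) without N2 B and the D libraries of N2 and PHX2193. PHX2193 against N2 (58, 35 over 2-fold) gave 451 (187) with DESeq2, 3 (3) with only the 8 libraries compared, 24 (19) with a replicate block, 394 (125) with sample quality weights, 4 (3) without the D libraries and 131 (56) without N2 B and the D libraries. PHX2193 against HBR2340 (3106) gave 5316 with only the 8 libraries, 6705 with sample quality weights and 5565 without N2 B and the D libraries. The replicate block gave 1053 genes for HBR2340 against N2 and 3063 between the strains. The letters do not pair the samples as a whole: libraries of the same letter deviated alike (r over 0.1) in 3 of 12 pairs, with a median r of −0.012. The highest was N2 D with PHX2193 D (r = 0.66), and N2 D correlated more with PHX2193 D (0.984) than with N2 A, B and C (0.972, 0.931 and 0.965). Leaving out 1 library gave 661 to 2880 genes (368 to 1016 over 2-fold) for HBR2340, 7 to 228 (6 to 89) for PHX2193, and 2237 to 5339 (1304 to 1971) between the strains. Lists passing fell from 12, 11 and 12 to 1, 1 and 0 with an estimated correlation, and PHX2193 against N2 gave 17 without N2 B and the D libraries. Leaving out 1 library gave 9 to 16, 8 to 16 and 8 to 15.

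Genes called in both strains with opposite sign (33) numbered 1 at adjusted p under 0.01 (with 1 of the same sign), 87 at 0.1 (with 3) and 141 without N2 B (with 11). With HBR2340 against N2 A and B and PHX2193 against the others, genes of opposite sign numbered 9. With A and C they numbered 158, A and D 110, B and C 0, B and D 2, and C and D 2. Genes of the same sign numbered 2 with A and D and 1 in each other split, so with B and C the same sign prevailed. Among genes and among lists that passed with all libraries, 4 and 2 values reversed. Lists that did not pass were compared only without N2 B, where 11, 11 and 0 of 42 medians changed sign in the 3 comparisons, and 5, 5 and 1 lists gained and 5, 3 and 4 lost their call. In PHX2193 against N2, where neither gene was called, egl-23 ranged from −0.17 to 0.11 and unc-58 from −0.108 to 0.0363 over the libraries left out. The heat shock list turned, without passing, with sample quality weights (adjusted p = 0.8001) and without N2 B and the D libraries (adjusted p = 0.583).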

Other observations

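The gene classes and the tests by position below were chosen after the results were seen.

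Gene classes by symbol overlap the lists in part. Genes of the clec, cpr, nlp, col and cyp classes are members of lists above, and several unc genes are body muscle markers. Tests of these classes therefore largely repeat list results, while ttr and nspc genes are in none of the lists. Among 201 classes, transthyretin-related genes (ttr) were overrepresented among the genes higher in HBR2340 than in N2, 8 of 47 (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0297), and among those lower in PHX2193 than in HBR2340, 15 of 47 (exact test, adjusted p = 0.00303). The unc class, named for uncoordinated movement, had 11 of 94 higher in HBR2340 (exact test, adjusted p = 0.0298), unc-52 and unc-58 among them. C-type lectins (clec) were lower in HBR2340 than in N2 in 16 of 111 (exact test, adjusted p = 0.000622) and higher in PHX2193 than in HBR2340 in 29 of 111 (exact test, adjusted p = 0.00025). Cathepsin B-like proteases (cpr) were lower in HBR2340 in 5 of 8 (exact test, adjusted p = 0.000532), and neuropeptide-like genes (nlp) in 14 of 65 (exact test, adjusted p = 4.7e-05).

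Between the strains, nuclear hormone receptor genes (nhr) were higher in PHX2193 than in HBR2340 in 37 of 211 (exact test, adjusted p = 0.0429), as were nspc genes in 6 of 10 (exact test, adjusted p = 0.0158). Collagens (col) were lower in 21 of 95 (exact test, adjusted p = 0.0160) and P450 genes (cyp) in 15 of 61 (exact test, adjusted p = 0.0269). The lists of cuticle collagens and of P450 and conjugation families did not pass in that comparison (camera adjusted p = 0.0758 and 0.0623, both 0.914 with an estimated correlation). The exact tests here treat genes as independent, which genes regulated together are not, so their p-values are too small.

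In N2 B the genes farthest above the other N2 libraries were acs-2, a fatty acid activating enzyme induced by fasting, 118.7-fold, F22B5.4, 112.8-fold, and phy-2, a collagen prolyl hydroxylase, 108.5-fold. The glyoxylate cycle gene icl-1 was 22.5-fold higher, the HIF-1 hydroxylase gene egl-9 21.9-fold and the gluconeogenesis gene pck-1 20.4-fold. These genes were picked after their values were seen.

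A hypothesis is that strain background adds to the calls. Chromosome V held 9 of the 24 genes called in PHX2193 only and 318 of the 1139 called in HBR2340 only (37.5 and 27.9%, one-sided Fisher's exact test, p = 0.208), so the test leaves a background on that chromosome open. Within 1 Mb of flp-11, 73 of 261 genes differed between the strains (27.97%), against 20.7% elsewhere on chromosome X (one-sided Fisher's exact test, p = 0.00539). Linked sequence differences may contribute to the latter, but genes that are neighbours are also often regulated together, which the test does not separate.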
